A study of Homo sapiens with 10 samples.

How the data were processed

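Long RNA and small RNA had been sequenced from BEAS-2B lines kept under G418 selection. Per the labels' protocols, RNA was isolated with the mirVana kit, ribosomal RNA was depleted before the NEBNext Ultra long RNA libraries were made, and the small RNA libraries came from the NEBNext small RNA kit. Per the submitters' processing notes the genome build was hg19 and the tools were Trimmomatic 0.36, Bowtie2 2.2.4, HISAT2, Cufflinks 2.2.1 and DESeq2. The notes give no role for each tool, no aligner settings, no gene annotation and no order of steps. The deposited long RNA tables hold raw counts from the authors for 57773 Ensembl genes, whole numbers with a different total in each library, and the deposited piRNA tables hold raw counts for 32826 identifiers, of which 3804 had a count in any library. The deposited miRNA tables hold a signal for 612 miRNAs that the authors had divided by 1 factor per library, since the values of a library are multiples of 1 step, between 0.659 and 1.27. All values up to 3000 steps lay within 0.05 of a whole number of steps, and dividing the totals by the steps gave 22294686 and 27538545 estimated reads for the empty vector and 22217596, 19904339 and 16077733 for TAF1C. How reads that match several genes or piRNAs were counted is not stated, and the tables hold no coordinates. Gene order for the test of neighbouring genes, and locus lengths, came from the RefSeq genes of GRCh38, matched by symbol or synonym.

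Of the miRNA names, 451 end in 5p, 19 in 3p and 142 carry no arm, so the arm is given as in the tables and was not checked. Zeros stand in the miRNA tables for 274 miRNAs, including 18 with a mean of at least 1000 in the libraries above 0. The miRNA test was therefore kept to the 338 above 0 in all libraries with a value of at least 10 in at least 2, a filter chosen after the zeros were seen. Symbols on more than 1 long RNA row, 236 of 55771, were summed to 1 gene, and 114 rows had no biotype.

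The groups were those of the labels, with 2 empty vector and 3 TAF1C libraries in each assay, and no covariate. Long RNA counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, for genes of at least 1 CPM in at least 2 libraries (18402 genes, 14332 of them protein coding). piRNA counts were tested with the robust fit of the same method for identifiers kept by filterByExpr (574). miRNA signal was tested on log2(value + 1) with limma 3.58.1 with a trend. All p were adjusted by Benjamini-Hochberg within each kind of RNA, two-sided, at 0.05. Gene lists with at least 3 tested members were tested with camera at an intergene correlation of 0.01, with an estimated correlation, and with fry, on log2 CPM with a prior count of 2 for the counts. The 35 long RNA lists covered the RNA polymerase I and III machinery, ribosome biogenesis, cytosolic ribosomal proteins, snoRNA hosts, S phase, G2 and mitosis, histones and MYC. They also covered epithelial and mesenchymal genes, matrix proteases, interferon, antigen presentation, inflammatory cytokines, p53, the unfolded protein response, heat shock, NRF2, hypoxia, cholesterol synthesis, TGF-beta with YAP, and immediate early genes. Others were lung cancer oncogenes, tumor suppressors, cancer-testis antigens, HOX genes, noncoding RNAs, the piRNA pathway, miRNA processing and mitochondrial mRNAs. Markers of haematopoietic, endothelial, airway and fibroblast cells completed them. The 10 miRNA lists were the let-7, miR-17-92, miR-200 and miR-34 families, miRNAs raised or lowered in lung cancer, the 14q32 and 19q13 clusters, miR-15/16 with miR-29, and haematopoietic and muscle miRNAs. After the data were examined, 6 lists were added for photoreceptors, neurons, glia, pigment cells, hepatocytes and skeletal muscle. The p of these 6 were adjusted among themselves, apart from the fixed lists. The piRNA to miRNA read ratio and the TAF1C level were tested by exact two-sided permutation, whose smallest p is 0.2 with 2 against 3 libraries. DESeq2 1.42.0 served as an alternative, and tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

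Named genes followed a rule fixed with the lists: TAF1C, then the 10 largest rises and the 10 largest falls among genes past the test whose groups did not overlap and whose mean was at least 5 CPM in the higher group. It also took the 3 changed members with the smallest adjusted p of each list that passed camera or had at least 3 changed members. For miRNAs the rule took the 8 largest rises and 8 largest falls with at least 100 CPM in the higher group, the 5 most abundant and 3 per list. For piRNAs it took 4 and 4 with the same minimum and the 3 most abundant, and for each marker list its most abundant marker. The text prints part of these. Members of the added lists, CKM, TF and GFAP among them, and the genes next to MYCN were named after their values were seen.

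The plan had assumed FPKM and miRNA counts. Alternatives that need FPKM (other pseudocounts, limma with and without a trend, FPKM as deposited) had no counterpart for long RNA counts, and library totals stood in for the last. Tests by chromosome were planned for tables with coordinates alone and were not run. Leaving out the 217 tested genes whose locus is under 300 bases was run, with 15711 genes matched to a locus and the others kept, and 18626 genes then passed the filter because CPM rose with the smaller totals. For the miRNA signal, filterByExpr and TMM gave way to limma on the deposited scale, median-of-ratios scaling stood in for size factors, and edgeR and DESeq2 ran on the recovered reads. Other alternatives were no filter, stricter filters, quantile normalization, other size factors, a replicate block, protein-coding genes alone, rows as deposited, zeros kept or taken as missing, and each library left out in turn. The replicate numbers were not shown to pair empty vector with TAF1C libraries. The deviations of libraries with the same number correlated across genes at 0.0427 and 0.135 in long RNA, where genes are not independent replicates. A block on the numbers was run as an alternative.

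The tests were checked on simulated data with the group sizes and counts of each table. The long RNA test recovered 25% of the genes changed 2-fold and 82% of those changed 4-fold, and called 12 of 18172 unchanged ones. For the other tables these were 91% and 100% and 6 of 354 for piRNAs, and 80% and 100% and 3 of 283 for miRNAs. A planted list of 30 genes gave a camera p of 4.58e-10. The simulated genes varied independently and with the same spread in both groups. These runs therefore do not check the tests under the wider spread of the empty vector long RNA libraries or under correlation within a list. The RNAs RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP, which ribosomal depletion leaves in, held 8.55% and 11.5% of long RNA counts in the empty vector libraries and 10.8%, 10.4% and 10.2% in the others.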

Results

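BEAS-2B, an immortalised human bronchial epithelial cell line, had been made into stable lines carrying either an empty vector or a vector for TAF1C. TAF1C is a subunit of SL1, the factor that places RNA polymerase I on the promoters of ribosomal RNA genes. The 10 samples fell into 4 groups: 2 empty vector and 3 TAF1C libraries of long RNA, and 2 empty vector and 3 TAF1C libraries of small RNA. The long RNA libraries held 22809601 and 28476151 gene counts with the empty vector and 37533366, 36481548 and 34212883 with TAF1C. In the small RNA libraries the miRNA values summed to 17820818 and 18160854 with the empty vector and 21407122, 22035505 and 20493894 with TAF1C, and the piRNA counts to 2820570 and 3586390, and 2527214, 2369904 and 2065555. The labels do not say whether the replicates were separate cultures, so each p measures the spread between these samples.

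The TAF1C transcript itself (ENSG00000103168) was not higher in the libraries labelled TAF1C. Its normalised read count, in CPM (counts scaled to library size, with TMM factors), was 71.1 ± 9.40 CPM (SD, n = 2) in the empty vector libraries and 63.3 ± 4.08 CPM (SD, n = 3) in the libraries labelled TAF1C. The log2 fold change was -0.17 ± 0.13 (SE), with an edgeR adjusted p = 0.353, and the difference of -7.71 CPM gave p = 0.4 in the exact two-sided permutation test, in which the smallest possible p is 0.2. Scaled by library totals alone, TAF1C fell by 0.38 on the log2 scale (edgeR adjusted p = 0.0316). Without empty vector replicate 1 it fell by 0.36 (adjusted p = 0.00133). Over all alternatives its log2 fold change ran from -0.38 to 0.02, above 0 with DESeq2 without a filter alone, and its adjusted p from 0.00133 to 0.975. Whether reads of the vector's transcript were counted at this gene is not given in the sources used here, and the labels were not tested by other means. The groups are therefore named by their labels throughout.

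The long RNA comparison asked which transcripts differed between the lines with the TAF1C vector and those with the empty vector, including genes active in cancer. By camera, secreted inflammatory signals and targets of TGF-beta and YAP were higher on balance in the libraries labelled TAF1C, while genes typical of photoreceptors and neurons were far lower. With an estimated correlation between genes, the neuronal list alone of these 4 passed (adjusted p = 0.0451). The neuronal and photoreceptor lists were drawn up after their levels were seen. Their p were adjusted apart from the fixed lists, among fewer lists. In the same camera test the fixed inflammatory list had a smaller unadjusted p (0.0029, against 0.0075 for the neuronal list) but an adjusted p = 0.101. These adjusted p therefore do not rank the lists. CXCL5, a chemokine that attracts neutrophils, was at 13.1 ± 0.980 CPM (SD, n = 2) in the empty vector libraries and 279 ± 12.2 CPM (SD, n = 3) in the libraries labelled TAF1C, 21.2-fold higher. MYC, a transcription factor that drives cell growth, was at 54.9 ± 7.57 CPM (SD, n = 2) in the empty vector libraries and 237 ± 10.5 CPM (SD, n = 3) in the libraries labelled TAF1C, 4.32-fold higher. OTX2, a transcription factor of the retina and forebrain, was at 303 and 425 CPM in the empty vector libraries and 0.228, 0.0588 and 0.124 CPM in the libraries labelled TAF1C.

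Of 18402 genes tested with edgeR quasi-likelihood, 2922 rose and 4158 fell at an adjusted p under 0.05, so that 41.3% of the changed genes were higher in the libraries labelled TAF1C, and 9105 genes had an unadjusted p under 0.05. The split moved with the scaling and the filter: the higher share was 31.1% with library totals (2269 and 5021 genes), 59.6% with quantile normalization (4303 and 2912) and 29.7% with no filter (1817 and 4304). The median log2 fold change of all tested genes was -0.10 with TMM, -0.33 with library totals and 0.22 with quantile normalization, and the changes below are relative to the TMM scale. Leaving out empty vector replicate 1 gave 4687 raised and 4759 lowered genes, and leaving out replicate 2 gave 5967 and 5665. These fits take the spread from the libraries labelled TAF1C alone. They test no gene under 1 CPM in all of these libraries, so gene lists can lose lowered members in them. Without TAF1C replicate 1, 2 or 3 the counts were 1058, 1182 and 1076 raised and 2043, 1960 and 2019 lowered. The empty vector libraries differed from each other more than the others did: the SD of the log2 difference was 0.648 between them and 0.158, 0.163 and 0.123 between the pairs labelled TAF1C. Of 16120 genes tested against each empty vector library alone, 3498 were raised and 3201 lowered against both, and 882 were called in opposite directions. The photoreceptor genes of a list drawn up after these levels were seen held 0.58% and 0.272% of all counts in the empty vector libraries and 0.00617%, 0.00496% and 0.00567% in the libraries labelled TAF1C.

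Of 35 gene lists fixed before the data were examined, 17 passed the camera test, each with its members higher on balance in the libraries labelled TAF1C, and 0 of the 35 passed camera with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry, 9 lists passed, 7 of the 17 and 2 others: the oncogenes and growth factors (up, adjusted p = 1.68e-05) and the differentiated airway markers (down, 0.0377). For every list that passed camera, the highest number of raised members with 1 library left out came from a fit with 1 empty vector library. The photoreceptor share given above and the wide spread of the empty vector libraries lie along the same split as each of these groups.

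**Figure D1:**
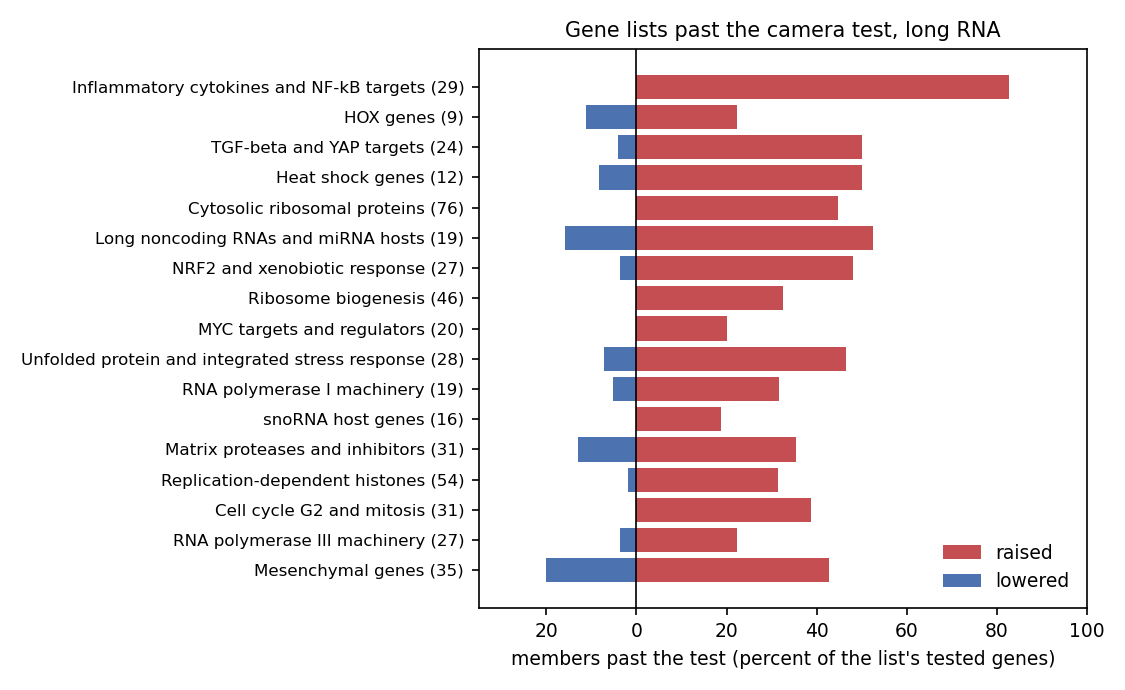
Percent of each list's tested genes (x axis) raised, to the right, or lowered, to the left, by edgeR in the long RNA libraries labelled TAF1C against the empty vector, for the 17 lists past camera, with the number of tested genes in brackets. The inflammatory list stands out with 24 of 29 genes raised.

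Inflammatory genes rose as a group by camera (camera adjusted p = 6.56e-14, and adjusted p = 0.101 with an estimated correlation). Of 29 tested cytokines and NF-kB targets, 24 rose and 5 did not pass the test, with 25 raised when adjusted over the list alone and 19 to 28 with 1 library left out. The list's median log2 fold change was 1.55. CSF3, the granulocyte growth factor, was at 3.51 ± 0.445 CPM (SD, n = 2) in the empty vector libraries and 43.3 ± 2.87 CPM (SD, n = 3) in the libraries labelled TAF1C, 12.3-fold higher. CXCL3, another neutrophil chemokine, had a log2 fold change of 3.66 ± 0.19 (SE) (edgeR adjusted p = 0.000259). Among type I interferon genes, 5 of 34 rose and 4 fell (3 and 4 adjusted over the list alone, 1 to 12 and 1 to 6 with 1 library left out, 12 and 1 without empty vector replicate 1). Their median was 0.01 and their mean -0.32, while camera pointed up (adjusted p = 0.377). The median was 0.41 without empty vector replicate 1 and -0.07 without replicate 2. LGALS3BP, a secreted glycoprotein, rose by 1.25 ± 0.11 (SE), whereas the antiviral enzyme RSAD2 was at 3.53 and 18.4 CPM in the empty vector libraries and 0.114, 0.176 and 0.186 CPM in the libraries labelled TAF1C. RSAD2 and CMPK2, another lowered gene of the list, were under 1 CPM in every library labelled TAF1C. Both were therefore not tested without empty vector replicate 1, and the counts and median of that fit cover fewer interferon genes. For antigen presentation, 1 of 7 genes rose (1 adjusted over the list alone, camera adjusted p = 0.332), with a median of -0.00184, a mean of 0.14 and a test that pointed up. Of these, 4 rose without empty vector replicate 1 (median 0.43), and 1 rose and 2 fell without replicate 2.

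**Figure D2:**
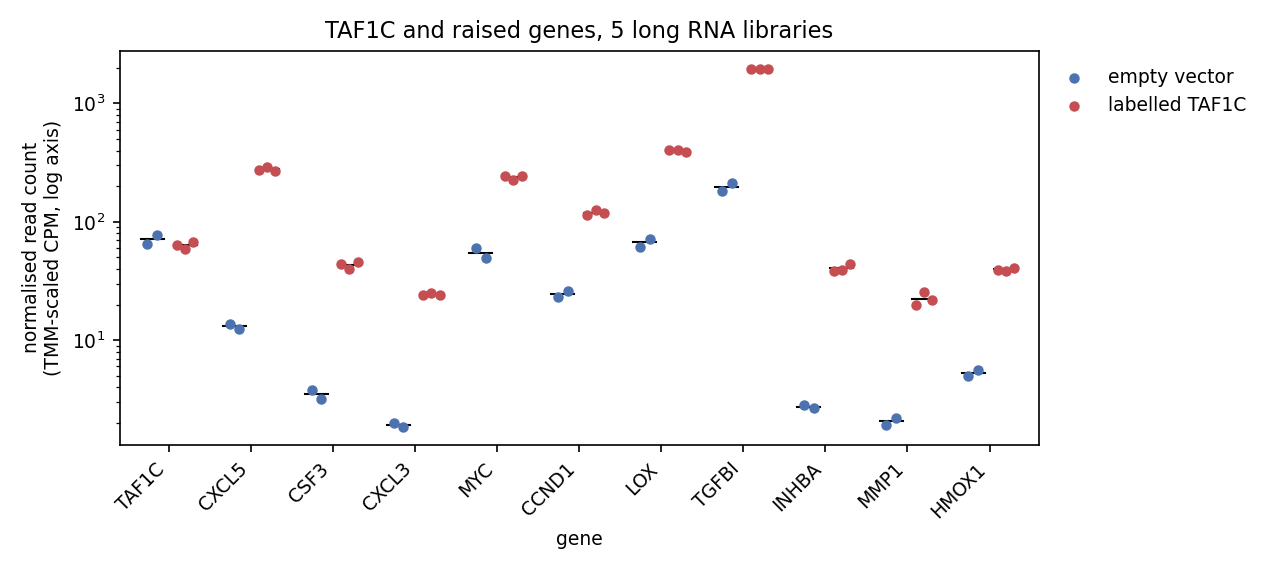
Normalised read count (TMM-scaled CPM, log axis) of TAF1C and 10 raised genes (x axis) in each long RNA library, with points for libraries and black lines for group means of the 2 empty vector libraries and the 3 labelled TAF1C. TAF1C was at 71.1 and 63.3 CPM, and CXCL5 at 13.1 and 279 CPM.

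Targets of TGF-beta and YAP, pathways that respond to growth factors and to tension, rose in 12 of 24 cases and fell in 1 (13 and 1 adjusted over the list alone, 11 to 19 raised and 1 to 4 lowered with 1 library left out). The TGF-beta and YAP list had a camera adjusted p = 8.82e-05, and adjusted p = 0.815 with an estimated correlation. INHBA, a subunit of the secreted signal activin, was at 2.75 ± 0.112 CPM (SD, n = 2) in the empty vector libraries and 40.5 ± 2.74 CPM (SD, n = 3) in the libraries labelled TAF1C, 14.7-fold higher. TGFBI, a matrix protein, rose by 3.30 ± 0.19 (SE) on the log2 scale. Among 35 mesenchymal genes, 15 rose, LOX, a collagen cross-linking enzyme, among them (2.57 ± 0.14 (SE)), and 7 fell (15 and 8 adjusted over the list alone, 11 to 20 and 5 to 16 with 1 library left out). The mesenchymal list had a camera adjusted p = 0.0350, and adjusted p = 0.815 with an estimated correlation. This call was lost without empty vector replicate 2 (camera adjusted p = 0.693, with 17 raised and 16 lowered), and the median of 0.26 turned to -0.22 there and to -0.04 with library totals (camera adjusted p 0.00694 to 0.693 over all alternatives). Matrix proteases and their inhibitors rose in 11 of 31 cases and fell in 4 (the same numbers adjusted over the list alone, 7 to 18 raised and 2 to 6 lowered with 1 library left out). The matrix protease list had a camera adjusted p = 0.0128, and adjusted p = 0.650 with an estimated correlation. Its call was lost without empty vector replicate 2 (camera adjusted p = 0.164, and 0.000178 to 0.164 over all alternatives). MMP1, a collagenase, rose by 3.43 ± 0.23 (SE), and TIMP1, an inhibitor of such enzymes, by 2.40 ± 0.11 (SE). The epithelial list split, with 9 of 38 genes raised and 8 lowered (9 and 9 adjusted over the list alone, 7 to 14 and 4 to 15 with 1 library left out). Its median of -0.21 and mean of -0.60 were negative while camera pointed up (adjusted p = 0.553). The median was 0.62 without empty vector replicate 1, where fewer genes of the list were tested, and 0.59 with quantile normalization. LAMB3, a chain of the basement membrane laminin, rose by 3.06 ± 0.19 (SE) and the keratin KRT8 by 1.74 ± 0.12 (SE), whereas the tight junction gene TJP3 had a log2 fold change of -5.51 ± 0.23 (SE).

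Growth regulators and genes known from lung cancer changed in both directions. Of 54 oncogenes and growth factors, 20 rose and 12 fell (21 and 15 adjusted over the list alone, 14 to 25 and 8 to 19 with 1 library left out). They had a median of 0.21, a mean of -0.34 and a camera adjusted p = 0.0572 in a test that pointed up, while they passed fry. The camera p was 0.0490 without TAF1C replicate 2, and 0.0185 to 0.407 over all alternatives. CCND1, the cyclin of the step into S phase, was at 24.7 ± 2.13 CPM (SD, n = 2) in the empty vector libraries and 119.6 ± 4.91 CPM (SD, n = 3) in the libraries labelled TAF1C, 4.85-fold higher. EREG, a ligand of the EGF receptor, rose by 2.80 ± 0.15 (SE) and CD44, a hyaluronan receptor, by 2.02 ± 0.12 (SE). MYCN, a relative of MYC active in neural tumours, was at 50.8 and 721 CPM in the empty vector libraries and 0.314, 0.206 and 0.309 CPM in the libraries labelled TAF1C. Of 43 tumor suppressors, 12 rose and 9 fell, in equal numbers adjusted over the list alone (6 to 18 and 6 to 17 with 1 library left out). Their camera adjusted p was 0.376, with a median of 0.16, -0.05 with library totals, and a mean of -0.36 beside a test that pointed up. CADM1, a cell adhesion molecule, had a log2 fold change of -6.65 ± 0.28 (SE) and the death kinase DAPK1 one of -5.13 ± 0.34 (SE), both higher in the empty vector libraries that carried the photoreceptor genes. The Wnt inhibitor DKK1 rose by 2.06 ± 0.15 (SE). Among cancer-testis antigens, genes of germ cells and tumours, 1 of 10 rose and 4 fell, as they did adjusted over the list alone (0 to 4 and 2 to 4 with 1 library left out; camera adjusted p = 0.627). PRAME, one of them, was at 16.9 and 155 CPM in the empty vector libraries and 0.342, 0.235 and 0.495 CPM in the libraries labelled TAF1C. The 26 p53 targets included 9 lowered genes (9 adjusted over the list alone) and 17 that did not pass. Their camera adjusted p was 0.0991, and 6.01e-05 without empty vector replicate 1 (20 lowered), and 6.01e-05 to 0.955 over all alternatives. Without empty vector replicate 2, 8 fell and 8 rose. TP53INP1, a stress gene, had a log2 fold change of -1.55 ± 0.12 (SE) and PPM1D, a phosphatase that dampens p53, one of -1.31 ± 0.14 (SE).

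Lists of genes for making ribosomes passed camera with most of their members not past the test. Cytosolic ribosomal proteins rose in 34 of 76 cases, with a median log2 fold change of 0.78 and 47 raised when adjusted over the list alone. This list had a camera adjusted p = 6.09e-12, and adjusted p = 0.815 with an estimated correlation. The number raised ran from 2 to 76 with 1 library left out, at 57 raised and 3 lowered without empty vector replicate 1 and 76 raised without replicate 2. The median was 0.38 and 1.15 in these fits and 0.30 with quantile normalization. RPL23A and RPL28, both of the large ribosomal subunit, rose by 1.05 ± 0.18 (SE) and 0.999 ± 0.15 (SE). Ribosome biogenesis factors rose in 15 of 46 cases (12 adjusted over the list alone, 3 to 45 raised and 0 to 7 lowered with 1 library left out). The biogenesis list had a camera adjusted p = 4.31e-06, and adjusted p = 0.815 with an estimated correlation. NOP16 rose by 1.40 ± 0.18 (SE) and BOP1 by 1.30 ± 0.18 (SE), both nucleolar proteins that process the RNA of the large subunit. In the RNA polymerase I list, which names the partners of TAF1C but not TAF1C, 6 of 19 genes rose and 1 fell, as adjusted over the list alone (3 to 15 raised and 0 to 5 lowered with 1 library left out). The RNA polymerase I list had a camera adjusted p = 0.0188, and adjusted p = 0.822 with an estimated correlation. POLR1E, a subunit of RNA polymerase I, rose by 1.03 ± 0.13 (SE). Of 27 RNA polymerase III genes, 6 rose and 1 fell, and 5 rose adjusted over the list alone (3 to 19 raised and 0 to 7 lowered with 1 library left out). The RNA polymerase III list had a camera adjusted p = 0.0210, and adjusted p = 0.815 with an estimated correlation. SNAPC1, which starts transcription of small nuclear RNA genes, rose by 1.74 ± 0.18 (SE), and MAF1, a repressor of RNA polymerase III, by 1.03 ± 0.17 (SE). Of 16 snoRNA host genes 3 rose, also when adjusted over the list alone (2 to 12 raised and 0 to 4 lowered with 1 library left out), SNHG8 by 1.16 ± 0.17 (SE). The snoRNA host list had a camera adjusted p = 0.0188, and adjusted p = 0.815 with an estimated correlation. Without empty vector replicate 1 the camera calls were lost for biogenesis (adjusted p = 0.0978), RNA polymerase I (0.663), RNA polymerase III (0.736, where the median turned to -0.01) and snoRNA hosts (0.727), and 7, 5, 7 and 4 of their genes fell. Their ranges over all alternatives were 9.59e-11 to 0.0978, 0.000655 to 0.663, 0.000564 to 0.736 and 0.000348 to 0.727.

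Of 31 G2 and mitosis genes, 12 rose and 19 did not pass, with 12 raised and 1 lowered adjusted over the list alone (1 to 28 raised and 0 to 4 lowered with 1 library left out). The G2 and mitosis list had a camera adjusted p = 0.000532, and adjusted p = 0.815 with an estimated correlation. AURKA, a kinase of the mitotic spindle, rose by 0.999 ± 0.17 (SE). Replication-dependent histones rose in 17 of 54 cases and fell in 1, also adjusted over the list alone (10 to 52 raised and 0 to 15 lowered with 1 library left out), HIST1H4L by 1.36 ± 0.14 (SE). The histone list had a camera adjusted p = 4.31e-06, and adjusted p = 0.815 with an estimated correlation. MYC targets and regulators rose in 4 of 20 cases, MYC itself and the amino acid transporter SLC7A5 (1.17 ± 0.21 (SE)) among them, with 3 raised adjusted over the list alone (2 to 18 raised and 0 to 3 lowered with 1 library left out). The MYC list had a camera adjusted p = 0.00196, and adjusted p = 0.815 with an estimated correlation. The S phase list did not pass, with 4 of 31 genes raised and 2 lowered (3 and 1 adjusted over the list alone, 1 to 18 and 0 to 15 with 1 library left out). Its camera adjusted p was 0.377, and 0.0439 to 0.972 over all alternatives. The median of 0.11 turned to -0.07 with library totals, -0.10 with quantile normalization and -0.17 without empty vector replicate 1. CDC45, part of the replicative helicase, rose by 0.75 ± 0.13 (SE). Without empty vector replicate 1 the camera calls of the G2, histone and MYC lists were lost, at adjusted p = 0.241, 0.305 and 0.193, with 4, 15 and 3 genes lowered, while over all alternatives they ran from 8.69e-06 to 0.312, 9.59e-11 to 0.472 and 1.33e-05 to 0.232.

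NRF2 targets, which protect against oxidants, rose in 13 of 27 cases and fell in 1, as they did adjusted over the list alone (9 to 18 raised and 0 to 4 lowered with 1 library left out). The NRF2 list had a camera adjusted p = 0.000207, and adjusted p = 0.815 with an estimated correlation. The haem-degrading enzyme HMOX1 rose by 2.90 ± 0.15 (SE) and ALDH1A3, which makes retinoic acid, by 2.46 ± 0.14 (SE). Heat shock genes rose in 6 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone, 2 to 11 raised and 0 to 1 lowered with 1 library left out). The heat shock list had a camera adjusted p = 0.00462, and adjusted p = 0.815 with an estimated correlation. With quantile normalization the first was 0.234, and 0.000149 to 0.234 over all alternatives. BAG3, a chaperone partner, rose by 1.70 ± 0.16 (SE). The unfolded protein and integrated stress list had 13 of 28 genes raised and 2 lowered (14 and 3 adjusted over the list alone, 7 to 23 raised and 0 to 10 lowered with 1 library left out). The stress list had a camera adjusted p = 0.00488, and adjusted p = 0.815 with an estimated correlation. The transcription factor CEBPB rose by 2.69 ± 0.16 (SE) and the stress kinase homologue TRIB3 by 1.27 ± 0.15 (SE). Its call was lost without empty vector replicate 1, where 10 genes fell (camera adjusted p = 0.655, and 0.000136 to 0.655 over all alternatives). Hypoxia and glycolysis genes rose in 8 and fell in 8 of 32 cases (8 and 9 adjusted over the list alone, 3 to 17 and 4 to 16 with 1 library left out). Camera gave an adjusted p = 0.568, with a median of 0.07, -0.20 with library totals, and a mean of -0.34 beside a test that pointed up. The vasodilator peptide gene ADM rose by 1.53 ± 0.12 (SE), while the neuronal enolase ENO2 had a log2 fold change of -3.79 ± 0.33 (SE), or -3.19 without empty vector replicate 1. Of 24 cholesterol synthesis genes 5 rose and 4 fell, as adjusted over the list alone (1 to 9 and 0 to 9 with 1 library left out). For these, camera gave an adjusted p = 0.803, with a median of -0.07 and a mean of -0.03 under a test that pointed up. DHCR7, the last enzyme of that pathway, rose by 1.38 ± 0.15 (SE).

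Among developmental and regulatory RNAs, the HOX list passed camera with 2 of 9 genes raised and 1 lowered (3 and 1 adjusted over the list alone, 1 to 5 raised and 0 lowered with 1 library left out). This list had a camera adjusted p = 0.0220, and adjusted p = 0.650 with an estimated correlation. With no filter its median of 1.10 turned to -0.70 and its camera adjusted p was 0.992, the highest of a range from 0.00694. The call was also lost without loci under 300 bases (0.0894) and with protein-coding genes alone (0.175). HOXA5, a patterning gene of the lung, rose by 1.71 ± 0.27 (SE). Of 19 long noncoding RNAs 10 rose and 3 fell, also adjusted over the list alone (6 to 12 raised and 1 to 6 lowered with 1 library left out). The noncoding RNA list had a camera adjusted p = 0.0462, and adjusted p = 0.815 with an estimated correlation. This call was lost without empty vector replicate 1 (0.0860) or 2 (0.359) (camera adjusted p, 0.00801 to 0.359 over all alternatives). CCAT1, a noncoding RNA transcribed upstream of MYC, was at 1.19 and 0.284 CPM in the empty vector libraries and 21.7, 19.6 and 21.2 CPM in the libraries labelled TAF1C, and MIR31HG, the host transcript of miR-31, rose by 2.58 ± 0.23 (SE). The immediate early list had 6 of 19 genes raised and 2 lowered (6 and 5 adjusted over the list alone, 5 to 9 raised and 2 to 6 lowered with 1 library left out). Its camera adjusted p of 0.260 ran from 0.0441 to 0.856 over all alternatives, with a median of 0.26, -0.03 with library totals, and a mean of -0.14 beside a test that pointed up. FOSL1, an AP-1 subunit, rose by 2.81 ± 0.14 (SE). For miRNA processing 3 of 21 genes rose and 5 fell (3 and 6 adjusted over the list alone, 1 to 8 and 2 to 12 with 1 library left out; camera adjusted p = 0.627, and 0.0151 to 0.992 over all alternatives). TNRC6C, a partner of Argonaute, had a log2 fold change of -5.69 ± 0.34 (SE). The piRNA pathway had 1 raised and 1 lowered of 13 (0 adjusted over the list alone by edgeR, 1 and 4 at an unadjusted p under 0.05, 2 and 2 by DESeq2, 0 to 3 and 0 to 4 with 1 library left out; camera adjusted p = 0.852). For the 13 mitochondrially encoded mRNAs edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.95). Their median was -0.18 in a test that pointed up, and up to 5 rose or 8 fell with 1 library left out.

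Markers of cell types other than bronchial epithelium were looked up in the same fit. No fixed marker list passed camera, and the airway list passed fry, pointing down (adjusted p = 0.0377). The haematopoietic list had 1 raised and 3 lowered of 11 (2 and 3 adjusted over the list alone, adjusted p = 0.641) and the endothelial list 2 lowered of 10 (5 adjusted over the list alone, 0.682). The differentiated airway list had 3 lowered of 9 (3 adjusted over the list alone, 0.602) and the fibroblast list 1 raised and 1 lowered of 10 (also adjusted over the list alone, 0.852). With 1 library left out, 0 to 5 haematopoietic markers rose and 1 to 4 fell, 0 to 2 endothelial markers rose and 0 to 6 fell, 0 to 2 airway markers rose and 2 to 3 fell, and 1 to 4 fibroblast markers rose and 1 to 6 fell. Without empty vector replicate 1 the medians were 0.80, 0.19, 0.05 and 0.73 in this order, against -0.17, -0.99, -1.34 and -0.15 with all libraries. Without replicate 2 they were -0.63, -1.64, 0.25 and -0.48. The airway median was positive in both fits, but these test fewer of its 9 markers. Markers under 1 CPM in every library labelled TAF1C drop out there, so the sign is not over the same markers. ABCA3, a lipid transporter of alveolar cells, was at 53.8 ± 10.998 CPM (SD, n = 2) in the empty vector libraries and 2.71 ± 0.683 CPM (SD, n = 3) in the libraries labelled TAF1C. The fibroblast matrix gene FBLN1 did not pass (log2 fold change -0.09 ± 0.13 (SE), adjusted p = 0.604), nor did the endothelial receptor TIE1 (0.43 ± 0.16 (SE), 0.0767). FBLN1 had an adjusted p of 0.00209 and TIE1 of 0.00326 without empty vector replicate 1, and over all alternatives they ran from 0.00209 to 0.980 and from 0.00326 to 0.448. HBB, a globin, was the most abundant haematopoietic marker, at 36.1 ± 6.18 CPM (SD, n = 2) in the empty vector libraries and 22.7 ± 1.83 CPM (SD, n = 3) in the libraries labelled TAF1C.

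Genes with no count in the libraries labelled TAF1C, given below, have limits only and could not be ranked. Among the others taken by the naming rule, the largest fall was that of SOX11, a neural transcription factor. It was at 116 CPM in the empty vector libraries and at 2 counts over the 3 libraries labelled TAF1C, both in replicate 2, a ratio of 5906 with a 95% counting interval of 1635 to 48764. NEUROD1, a transcription factor of neurons and photoreceptors, was at 216 and 189.9 CPM in the empty vector libraries and 0.0570, 0.118 and 0.0928 CPM in the libraries labelled TAF1C. AMER2, a Wnt regulator of neural tissue, and DCT, an enzyme of melanin synthesis, were at 509.9 and 334 CPM, and 820.4 and 147 CPM, in the empty vector libraries and averaged 0.307 and 0.357 CPM in the others. 4 genes had no count in the libraries labelled TAF1C: against a floor of 3 counts over the group, the actin-binding thymosin gene TMSB15A was at least 349-fold lower, RP11-1085N6.6 at least 395-fold, AC011755.1 at least 342-fold and the pseudogene RPL35AP31 at least 192-fold. AC011755.1 was at 17.988 and 2.27 CPM and RPL35AP31 at 8.73 and 2.63 CPM in the empty vector libraries. Their limits were 76.9-fold and 88.9-fold without replicate 1 and 608-fold and 295-fold without replicate 2. The call of AC011755.1 was lost without TAF1C replicate 2 (edgeR adjusted p = 0.0553, the highest of its alternatives, whose lowest was 3.73e-05). Such intervals and floors cover counting error only. Of the 4158 lowered genes, 1323 were under 1 CPM in every library labelled TAF1C. By the same rule the largest rise was that of VAMP7, a vesicle fusion protein. It was at 0.0743 and 0.320 CPM in the empty vector libraries and 6.13, 11.9 and 0.526 CPM in the libraries labelled TAF1C (edgeR adjusted p = 0.0473). This call was lost with library totals (0.0518), and its adjusted p ran from 8.54e-05 to 0.0528 over all alternatives. Next came CCAT1 and ALOX5AP, a protein of leukotriene synthesis (4.55 ± 0.32 (SE)). Without empty vector replicate 1 or 2, the log2 fold change was 4.19 or 6.28 for VAMP7 and 6.11 or 4.09 for CCAT1, and VAMP7 was not tested without TAF1C replicate 1 or 2.

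After these values were seen, 6 lists of cell type genes were drawn up, so their results are no independent evidence. Photoreceptor genes fell in 25 of 28 cases (27 adjusted over the list alone), with a median log2 fold change of -6.09 (camera adjusted p = 8.28e-09, and adjusted p = 0.475 with an estimated correlation). The cone-rod transcription factor CRX was at 212 and 362 CPM in the empty vector libraries and 1.65, 1.03 and 1.45 CPM in the libraries labelled TAF1C. IMPG2, a proteoglycan of the photoreceptor matrix, was at 869 and 680.1 CPM in the empty vector libraries and RBP3, its retinoid carrier, at 508 and 133 CPM. Neuronal and neuroendocrine genes fell in 18 of 19 cases, also adjusted over the list alone, with a median of -5.53 (camera adjusted p = 8.28e-09, and adjusted p = 0.0451 with an estimated correlation). SYP, a synaptic vesicle protein, had a log2 fold change of -5.95 ± 0.23 (SE) and the axonal motor KIF1A one of -6.60 ± 0.30 (SE). The other lists did not pass camera: glial (0 of 5 called by edgeR, 2 lowered at an unadjusted p under 0.05 and 2 by DESeq2, camera adjusted p = 0.611) and pigment cell (1 raised and 1 lowered of 6, 0.865), and likewise hepatocyte (1 raised of 3, 0.328) and skeletal muscle (2 lowered of 5, 0.611). Adjusted over the list alone, 1 pigment gene rose and 1 fell, 1 hepatocyte gene rose and 1 fell, and 2 muscle genes fell. By fry the muscle list passed, pointing down (adjusted p = 0.000122), and the hepatocyte list, pointing up (adjusted p = 0.00155) with a median of 0.48 and a mean of -1.10. TTN, the giant sarcomere protein, was at 1775 and 2011 CPM in the empty vector libraries and 71.2, 72.7 and 73.6 CPM in the libraries labelled TAF1C. The 2 empty vector libraries did not carry one profile: the muscle enzyme CKM was at 0.780 and 76.4 CPM, transferrin (TF) at 106 and 0.320, and the glial filament GFAP at 38.6 and 1.39. CKM, called in the fit of all 5 libraries (edgeR adjusted p = 0.0459), had a log2 fold change of -5.11 that turned to 0.48 without empty vector replicate 2 (adjusted p = 0.487, and 4.45e-24 to 0.557 over all alternatives).

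**Figure D3:**
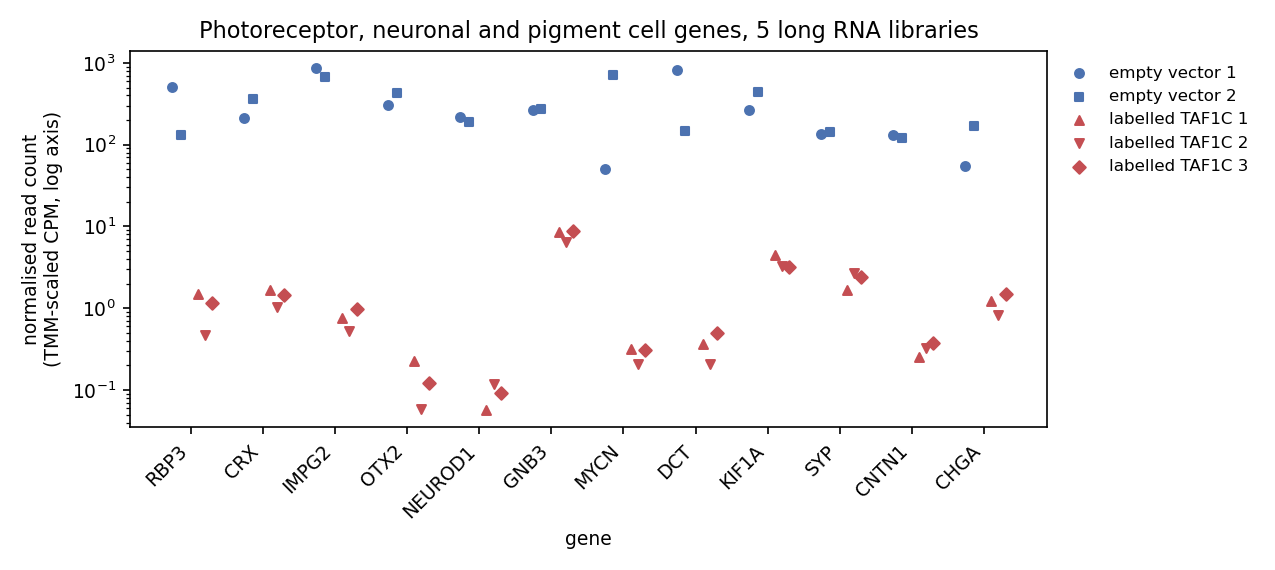
Normalised read count (TMM-scaled CPM, log axis) of 12 photoreceptor, neuronal and pigment cell genes (x axis) in each long RNA library, with 1 symbol per library. All 12 were lower in each library labelled TAF1C than in either empty vector library, and MYCN stood at 50.8 and 721 CPM in the latter.

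The small RNA comparison asked whether miRNAs differed between the same lines. Among tested miRNAs of at least 100 CPM in the higher group, miR-9-5p, a miRNA of neural tissue, fell the most. Its deposited signal was 15482 ± 863 (SD, n = 2) in the empty vector libraries and 384 ± 60.7 (SD, n = 3) in the libraries labelled TAF1C, 40.5-fold lower. Left out of the test for its zeros, miR-149-5p stood at 10448 and 10629 in the empty vector libraries and 0 in the others. Likewise left out, miR-577 stood at 2763 and 2429 against 0, 11.1 and 0. Such zeros are weighed below. miR-146a-5p, which NF-kB induces and which dampens cytokine signalling, was at 13396 ± 672 (SD, n = 2) in the empty vector libraries and 37624 ± 661 (SD, n = 3) in the libraries labelled TAF1C, 2.81-fold higher. miR-31-5p, cut from the transcript MIR31HG, was at 106070 ± 10096 (SD, n = 2) in the empty vector libraries and 228890 ± 18207 (SD, n = 3) in the libraries labelled TAF1C, 2.16-fold higher. miR-210, a miRNA of the hypoxia response listed with the 5p arm, fell by 1.40 on the log2 scale.

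With limma, 71 of 338 miRNAs rose and 65 fell, 52.2% of them higher, and 166 had an unadjusted p under 0.05. With library totals the numbers were 40 and 127 (24.0% higher), and the median log2 fold change of all tested miRNAs was 0.02 as deposited and -0.22 with library totals. Without empty vector replicate 1, 41 fell. TAF1C replicate 1 stood apart: the SD of the log2 difference was 0.474 and 0.433 between it and replicates 2 and 3, 0.141 between these and 0.154 between the empty vector libraries, and without it 90 rose and 88 fell. Beyond miR-146a-5p and miR-31-5p, the largest rise among tested miRNAs of at least 100 CPM in the higher group was in miR-671-5p (1.41 ± 0.08 (SE), limma adjusted p = 2.84e-06). Next came miR-7-5p (1.17 ± 0.07 (SE)), which targets the EGF receptor, miR-200c, listed with the 5p arm (1.01 ± 0.09 (SE)), and miR-99a-5p (1.01 ± 0.08 (SE)). Falls with the same minimum were in miR-199b-5p (log2 fold change -2.22 ± 0.15 (SE)), miR-340-5p (-1.06 ± 0.07 (SE)) and miR-589-5p (-0.96 ± 0.09 (SE)). The most abundant miRNA in every library was miR-21-5p, a growth-promoting miRNA, which rose by 0.69 ± 0.06 (SE). Quantile normalization sets the top miRNA of every library to one value, so the rise of miR-21-5p was lost there, with an adjusted p of 1 against 1.03e-29 as the lowest of all alternatives. miR-20a-5p, of the miR-17-92 cluster, rose by 0.45 ± 0.08 (SE), but its call was lost with library totals (limma adjusted p = 0.0941, the highest of its alternatives, with 4.85e-09 the lowest). miR-26a-5p had a log2 fold change of -0.41 ± 0.06 (SE). let-7a-5p did not pass (0.14 ± 0.08 (SE), limma adjusted p = 0.184), except without TAF1C replicate 1 (0.00207, and 0.00207 to 1 over all alternatives), and its sign turned with library totals (-0.11).

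**Figure D4:**
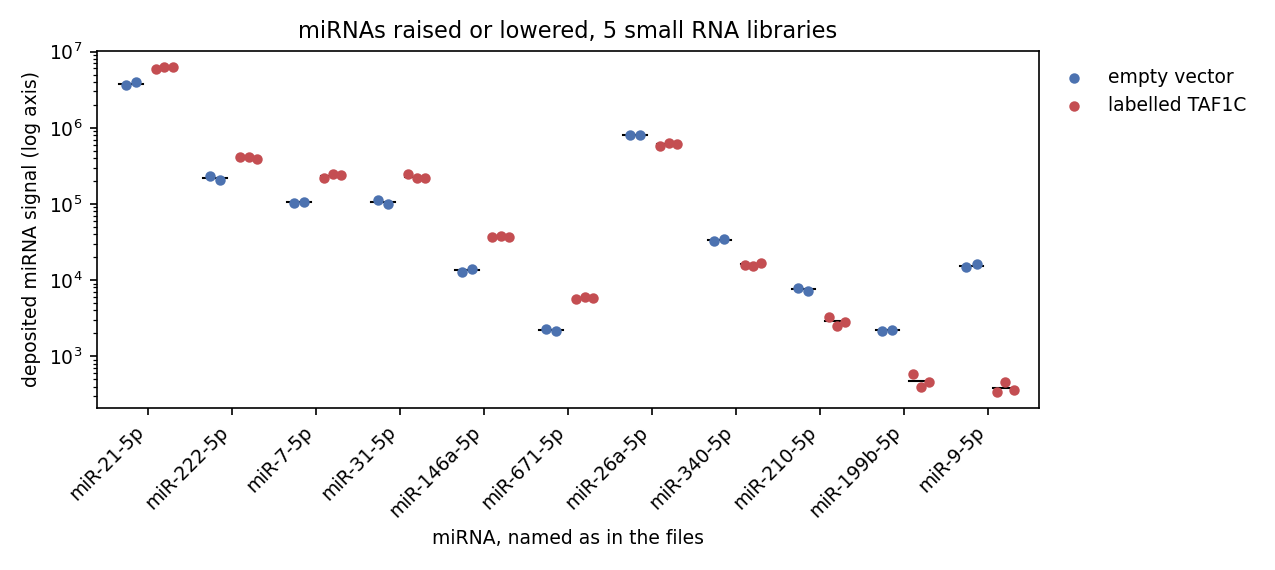
Deposited miRNA signal (log axis) of 11 miRNAs (x axis) in each small RNA library, with points for libraries and black lines for the means of the 2 empty vector libraries and the 3 labelled TAF1C. miR-9-5p was at 15482 and 384.

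Of the 10 miRNA lists, fixed likewise, 7 had at least 3 tested members by exact name. None passed camera or fry: 0 lists were past either test, with 0 at an unadjusted camera p under 0.05 (the lowest was 0.0876) and 3 at an unadjusted fry p under 0.05. Each list's calls were the same or within 1 miRNA by edgeR on recovered reads, but several moved further with library totals. The let-7 family, growth-restraining miRNAs, had 4 of 7 lowered (4 adjusted over the list alone, camera adjusted p = 0.613), including miR-98-5p at -0.72 ± 0.07 (SE). Of this family 2 fell without empty vector replicate 2, 5 with library totals and 1 to 5 over all alternatives, and 1 rose without TAF1C replicate 1. For the miR-17-92 cluster and its paralogs, 3 of 5 rose (3 adjusted over the list alone, 0.672), but 1 without empty vector replicate 2 and 0 with library totals, where 2 fell. Among miRNAs described as raised in lung cancer, 4 of 11 rose and 5 fell (4 and 5 adjusted over the list alone, 0.672; 3 and 7 with library totals, and 3 lowered without empty vector replicate 2). Among those described as lowered, 3 of 11 rose and 3 fell (3 and 3 adjusted over the list alone, 0.989; 2 and 6 with library totals, and 1 lowered without empty vector replicate 1 or TAF1C replicate 2 or 3). miR-218-5p rose by 1.57 ± 0.11 (SE), and miR-138-5p had a log2 fold change of -1.28 ± 0.12 (SE). The miR-34 family, targets of p53, had 0 of 3 called by limma, 1 at an unadjusted p under 0.05, 1 by edgeR and 0 by DESeq2 (camera adjusted p = 0.838). Without TAF1C replicate 1, miR-34a-5p passed (limma adjusted p = 0.000117, and 0.000117 to 0.703 over all alternatives). The miR-15/16 and miR-29 list had 1 of 5 lowered, miR-15b-5p (1 adjusted over the list alone, 0.672), and the haematopoietic and muscle markers 1 of 5 raised, miR-142-5p (1 adjusted over the list alone, 0.672). With library totals 4 of the former fell, and of the latter 1 rose and 1 fell. Without TAF1C replicate 1, 1 of the former rose and 2 fell, and 2 of the latter rose. By exact name the miR-200 family had 1 tested member, miR-429, which rose by 1.11 ± 0.18 (SE), the 14q32 cluster 1, miR-379-5p, which had a log2 fold change of -1.63 ± 0.31 (SE), and the 19q13 cluster 0. Names were also matched without arm, a choice made after the names were seen. Then 4 of 4 members of the miR-200 family, repressors of the mesenchymal state, rose (median 1.06, camera adjusted p = 0.0154, and adjusted p = 0.473 with an estimated correlation). No other list passed camera under this matching. The miR-15/16 and miR-29 list had 3 raised and 2 lowered of 9, and the miR-17-92 list 5 raised of 10. The lists lowered and raised in lung cancer had 6 raised and 4 lowered of 18, and 6 raised and 6 lowered of 14.

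The same small RNA libraries were compared for piRNAs, short RNAs known for silencing transposons in germ cells. The 3 most abundant identifiers, piR-hsa-11361, piR-hsa-11360 and piR-hsa-11362, made up 74.6% and 75.2% of piRNA counts in the empty vector libraries and 62.6%, 65.9% and 66.4% in the libraries labelled TAF1C. Among identifiers of at least 100 CPM in the higher group, the largest fall was in piR-hsa-1556, at 124 ± 7.61 CPM (SD, n = 2) in the empty vector libraries and 34.7 ± 3.08 CPM (SD, n = 3) in the libraries labelled TAF1C. The largest rise among these was in piR-hsa-3405, at 256 ± 24.7 CPM (SD, n = 2) in the empty vector libraries and 665 ± 40.1 CPM (SD, n = 3) in the libraries labelled TAF1C. These values are CPM over the piRNA counts. With edgeR, 87 of 574 identifiers rose and 81 fell (51.8% higher), and 214 had an unadjusted p under 0.05. The split moved with the scaling, to 208 and 40 with library totals (83.9% higher) and to 267 and 34 with the combined size of the miRNA and piRNA reads (88.7% higher). The median log2 fold change of all tested identifiers was 0.05, 0.36 and 0.47 under these scalings. piR-hsa-24775 rose by 1.30 ± 0.10 (SE) (edgeR adjusted p = 6.54e-11), and piR-hsa-28488 had a log2 fold change of -1.80 ± 0.11 (SE) (1.28e-12). piR-hsa-11360 and piR-hsa-11362 had log2 fold changes of -0.77 ± 0.07 (SE) and -0.82 ± 0.08 (SE). That of piR-hsa-11361 was -0.34 ± 0.07 (SE) (0.000500), and its call was lost with library totals (-0.03) and its sign turned with the combined size (0.09), with adjusted p from 1.05e-06 to 0.674 over all alternatives. Whether the reads assigned to piRNA identifiers came from piRNAs was not tested. They amounted to 12.8 ± 0.263% (SD, n = 2) of estimated miRNA reads in the empty vector libraries and 12.043 ± 0.746% (SD, n = 3) in the others. The exact two-sided permutation test of the difference of -0.79 gave p = 0.4, with 0.2 the smallest p it can give. With 1 library left out the difference ran from -1.20 without TAF1C replicate 3 to -0.46 without TAF1C replicate 1.

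**Figure D5:**
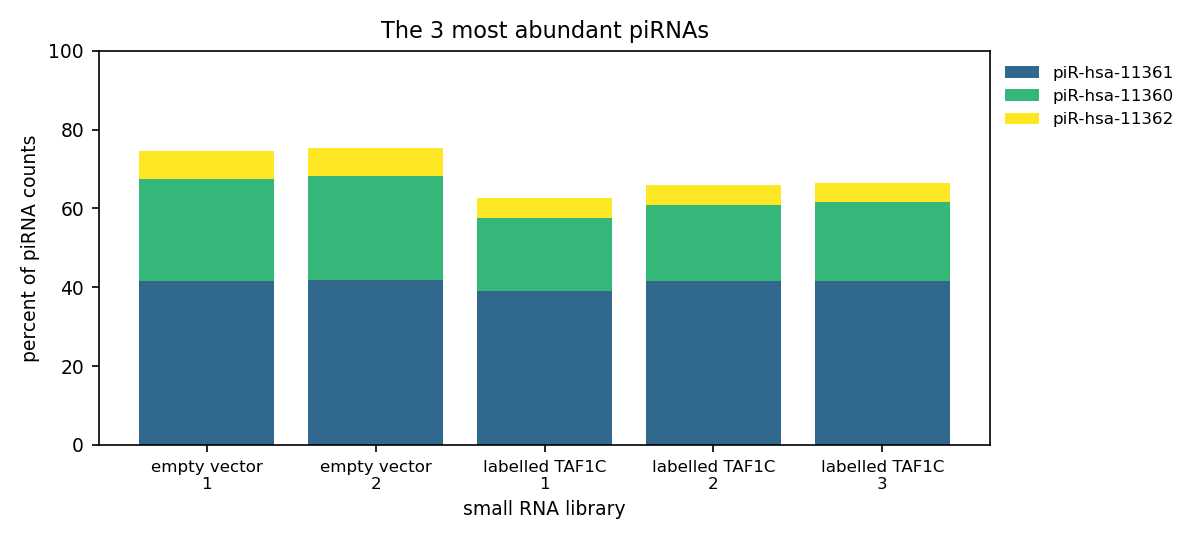
Percent of piRNA counts (y axis) in each small RNA library (x axis) held by the 3 most abundant piRNA identifiers, stacked. Together they reached 74.6% and 75.2% with the empty vector and 62.6%, 65.9% and 66.4% in the libraries labelled TAF1C.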

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

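All tests in this part were chosen after the result they weigh was seen, except the test of neighbouring genes, whose bound was set beforehand and judged unsound after. 1 value stood apart in data that the reported miRNA test left out, though alternatives that kept zeros used it: miR-24-2-5p was listed at 309729 on average over the 3 libraries labelled TAF1C (293564, 317114 and 318511) and at 0 in both empty vector libraries.

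Photoreceptor and neuronal transcripts stood in the empty vector long RNA libraries, and material of other cells is weighed here as an explanation. The tables argue against 1 cell state shared by both libraries. The log2 difference between them had an SD of 2.11 over the 25 lowered photoreceptor genes, 4.09 times the 0.515 over 7658 other genes. These others had the same empty vector level and at least 20 CPM in the mean of the libraries labelled TAF1C. The SD was 2.14 over 135 genes of at least 20 CPM in the empty vector mean and under 1 CPM in every other library. It was 0.805 over the other 8325 genes with that empty vector minimum. Whether other material that differs between the libraries was there stays open. The correlation of a gene's difference with that of its 10 neighbours, 0.154, did not exceed the highest of those between libraries labelled TAF1C (0.272, 0.0243 and 0.275) and so met the bound set against the explanation. That bound was not sound, because the latter 3 differ from each other by more than its margin, although photoreceptor genes held at most 0.00617% of counts in these libraries. The covariance ran the other way, at 0.0380 for the empty vector libraries and at most 0.00454 for pairs labelled TAF1C. A covariance also grows with the wider spread between the empty vector libraries, so it does not decide either. In a single empty vector library each, 43 genes were at 50 CPM or more and over 16 times the level elsewhere (33 in replicate 1, 10 in replicate 2, and 0 in each library labelled TAF1C by the same count), as such material would need, but this count does not tell it from lines that differ. Whether the small RNA libraries held such material stays open. Retina-enriched miRNAs above 0 in all libraries had a median log2 excess of 0.456 in the empty vector, between the bounds set. They were miR-183-5p (0.46), miR-96-5p (0.45), miR-9-5p (5.34) and miR-124-5p (-0.89) alone. The listed miR-182-5p, at 6095 in empty vector replicate 1 and 0 in every other library, was left out for its zeros. A difference between the stable lines, which the design names, was not separately tested.

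Cytokine and NF-kB target transcripts were higher in the libraries labelled TAF1C. Dilution of 1 shared profile in the empty vector libraries by material that lacks these transcripts is argued against by the spread of the changes. Over 17 genes of at least 20 CPM the log2 fold changes ran from 0.87 to 4.41 with an SD of 1.04. That was 3.34 times the SD between the empty vector libraries, where such dilution would move all by about one amount. Material that carries some of these transcripts would spread the changes by gene, so dilution by it stays open. In the libraries as sequenced, a higher level of the TAF1C transcript as counted at its gene is argued against as well. Its log2 fold change plus 2 SE was 0.0951, though DESeq2 without a filter gave 0.023 ± 0.35 (SE), which is less tight. Other material in the empty vector libraries, left open above, could add its own TAF1C counts there. A higher level in the cells labelled TAF1C therefore stays open. A vector transcript that these counts miss, wrong labels and a difference between the 2 sets of stable lines stay open and were not tested.

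Abundant miRNAs stood at 0 in some small RNA libraries, and 15 of 18 such miRNAs were at 0 in 1 library and at 1000 or more in another of the same group. Leaving those 15 out of a library's list although their reads were there would give this, but so would listing reads under another name. The count does not tell these apart. miR-23a-5p and miR-23b-5p, both among the 15, stood at 0 and 66820 in empty vector replicate 1 and at 53991 and 0 in replicate 2. In TAF1C replicates 1, 2 and 3 they stood at 74049 and 0, 0 and 55224, and 65059 and 52791. Not among the 15 were miR-24-2-5p, miR-149-5p and miR-577, so the count does not bear on these. Too few reads in a library is argued against by its depth, since the library with the fewest estimated reads had 58.4% of those of the deepest. For miR-24-2-5p, miR-23a-5p is cut from the same primary transcript and was listed at 53991 in empty vector replicate 2. Because miR-23a-5p is among the 15 and alternates with miR-23b-5p as given above, this value cannot decide whether that transcript was absent there. No biological explanation was tested beyond that.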

How the results depend on the processing

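Alternatives with protein-coding genes alone, library totals and size factors in edgeR for long RNA, and for small RNA zeros kept or missing, no trend, quantile normalization, edgeR on recovered reads, a piRNA fit that is not robust and arm-free names, were chosen after the data were examined. Of 17 long RNA lists past camera, 4 passed in every setting (inflammatory, ribosomal proteins, NRF2, TGF-beta and YAP), 10 calls were lost with quantile normalization, 9 without empty vector replicate 1, 3 without replicate 2, 5 at a minimum of 5 CPM, 3 with protein-coding genes alone and 1 each with no filter and without loci under 300 bases (the HOX list in both). In all, 10 long RNA lists passed with quantile normalization and 10 to 18 with 1 library left out. Raised genes numbered 1817 with no filter, 1425 with the block and 1058 to 5967 with 1 library left out, and lowered genes 2662 and 1960 to 5665. The TAF1C log2 fold change was -0.38 with library totals and -0.36 to -0.057 with 1 library left out, and turned to 0.023 with DESeq2 without a filter. With library totals 40 miRNAs rose and 127 fell, and 41 to 88 fell with 1 library left out. Raised piRNAs numbered 208 with library totals and 267 with the combined size, and lowered piRNAs 40 and 34. Of 116 named genes past the test, 96 were so in every setting that tested them, as were 23 of 30 miRNAs and 10 of 11 piRNAs, and 16 gene calls were lost without each TAF1C library and 13 with the block. With 1 library left out the sign turned for MAP2 (-0.32 to 1.07), SLC1A3 (-1.42 to 1.32) and CKM (-6.16 to 0.48), each past the test in the fit of all libraries or in the fit that turned it. It also turned, past the test in neither of these 2 fits, for TF (-6.74 to 1.57), GFAP (-4.34 to 0.43), TNNT1, TNNT3, MYH7, PMEL, MBP, SOX10 and FBLN1, and piR-hsa-11361 turned to 0.088 with the combined size. The fits with 1 empty vector library assume that it varies like the libraries labelled TAF1C and test no gene under 1 CPM in all of these, and a fit without a TAF1C library has fewer samples. For the other changes the cause was not tested. DESeq2 and zeros taken as missing gave no list test, and the FPKM alternatives were not run. Depth limits what can be seen near the filter of 1 CPM.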

Other observations

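Genes next to MYCN were looked at after its values were seen. In empty vector replicate 2, DDX1 was at 2169 CPM, NBAS at 713 CPM and the antisense transcript MYCNOS at 99.3 CPM, against 67.9, 68.1 and 6.50 CPM in replicate 1. The median log2 difference between these libraries over the 10 neighbours of MYCN was 0.687, and 246 of 11676 genes had neighbours with a higher median. The difference was 3.38 for NBAS, 4.99 for DDX1 and 3.83 for MYCNOS. For the other neighbours it ran from -1.12 (TRIB2) to 1.08 (SMC6), and the median mostly reflects these.

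Single genes of empty vector replicate 1 included the photoreceptor calcium sensor RCVRN, at 255 CPM against 1.07 CPM in replicate 2 and at most 0.770 CPM elsewhere, and the retinal transporter ABCA4, at 163 against 4.73 and at most 3.17 CPM. In replicate 2 the neurofilament NEFH was at 134 CPM against 6.58 in replicate 1 and at most 1.28 CPM elsewhere. Of the miRNAs left out of the tests, miR-100-5p was listed at 1176260 and 1220530 in the empty vector libraries and at 1447580, 1619850 and 0 in the libraries labelled TAF1C, miR-149-5p at 10448 and 10628.7 against 0 in all 3, and miR-182-5p at 6095 in empty vector replicate 1 alone. Without the most abundant identifier, the difference in the piRNA to miRNA read percentage was -0.37 (exact two-sided permutation p = 0.4), and over miRNAs listed in all libraries it was -0.94 (p = 0.2).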
